A study of Mus musculus with 12 samples.

How the data were processed

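Gene expression was measured on 12 spotted oligonucleotide arrays with 2 dyes each. Per the labels, IB10 (E14) mouse embryonic stem cells were infected with lentiviral pLKO-puro vectors that carried a control hairpin, shKdm5c#1 or shKdm5c#2, and puromycin was added 24 h after the last infection. The labels state that surviving colonies were pooled into polyclonal lines, that cells grew on gelatin in serum with LIF, and that total RNA was made with Trizol. Each line had 4 cultures, A to D, and each array carried 1 culture and, per the labels, a common reference RNA of untreated IB10 cells, taken here as 1 preparation. Per the labels, the sample was in Cy3 in cultures A and C and in Cy5 in cultures B and D.

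For each array the deposited raw file holds the intensity of each spot and of its local background in both channels, per the file headers, with no background subtraction or normalization. A derived file per array holds intensity per dye as normalized by the authors, on a linear scale, with no method given in the sources used here. The deposited table of values holds log2 of the authors' normalized Cy5 signal over Cy3 signal, which was checked on all 12 arrays against the derived files (largest difference 5.00e-10). Its values are therefore Cy5 over Cy3 whatever dye held the sample, with column medians of -0.0026 to 0.016. Scale and direction of this table are thus known from the values, while the method of normalization stays unknown. Channel 1 of the raw files is Cy5, per the labels and by its correlation with the authors' Cy5 signal (lowest r = 0.999783).

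The comparisons rest on the raw files. Each array holds 45220 spots, 41174 for genes and 4046 controls. Background was removed in limma 3.58.1 under R 4.3.3 with normexp and an offset of 50, and ratios were normalized within each array by loess over intensity, with control spots at weight 0. Ratios were then turned to sample over reference. Probes with a symbol numbered 34186, each with 1 symbol and 0 with several, and 6988 probes had no symbol. Of the 18322 symbols, kept as the array file spells them, 16254 stood in the RefSeq gene table of GRCm38.p6 and 2051 only among its synonyms. The probe with the highest mean intensity stood for each gene, which set aside other probes for 8938 genes. Genes were not filtered by intensity, and no array was left out.

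A gene spot counted as above background when its median signal passed the background median by 2 background SDs. Between 84.4 and 96.4 percent of gene spots per array passed in the sample channel. Median signals were 94.5 to 163 in Cy5 and 103 to 149 in Cy3 over backgrounds of 34 to 37. In the sample channel, 0 to 21 gene spots per array passed 65000, near the top of the scale, and the reference channel was not counted. Residual SDs per array ran from 0.05 to 0.06 log2, apart from 0.08 in culture D of shKdm5c#2. With dye effects removed, ratios of the cultures of a line correlated at r = 0.508 to 0.847, lowest between cultures B and D of shKdm5c#2.

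A linear model with a term per line and a dye term was fitted to all 12 arrays, with 8 residual degrees of freedom and 7.64 more from limma's empirical Bayes step. The contrasts were shKdm5c#1 and shKdm5c#2 against control, their mean against control, shKdm5c#1 against shKdm5c#2, and the control line against the reference. P-values are limma's moderated ones, adjusted by Benjamini-Hochberg over 18322 genes in each contrast, with 0.05 as the threshold. A gene counted as changed in both knockdowns when it was called with the same sign in each. Because both contrasts share the control arrays, the overlap was set against 20 simulations without effects and against fits with the controls divided between the contrasts. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

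The gene lists, 27 in number and written from general knowledge, were H3K4 demethylases, H3K4 methyltransferase complexes, Polycomb components, pluripotency factors, LIF and Stat3 targets, FGF and ERK feedback targets, epiblast (primed) markers, germline genes, 2-cell-stage genes, extraembryonic endoderm, mesoderm and primitive streak, neuroectoderm, synaptic and neuronal function, trophectoderm, fibroblast and feeder markers, Hox genes, clustered protocadherins, imprinted genes, interferon response, p53 targets, G2 and M phase genes, S phase and replication, cholesterol synthesis, glycolysis and hypoxia, unfolded protein and amino acid stress response, cytosolic ribosomal proteins and replication-dependent histones. They were tested with limma's camera at its preset correlation of 0.01 and again with the correlation estimated per list. Some genes stand in several lists, such as Krt8 and Krt18 among trophectoderm and extraembryonic endoderm markers. The list of replication-dependent histones took every gene with a symbol of the histone clusters, and replication dependence of its members was not checked.

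Genes named in the text come from a rule. It takes Kdm5c and the other H3K4 demethylases, and the 10 highest and 10 lowest genes changed in both knockdowns by their mean log2 change. It also takes the 10 highest and 10 lowest called genes of every other comparison, and up to 4 members per list with the smallest adjusted p. The text names part of these and says where a gene was chosen after its values were seen. Groups, comparisons, lists, this rule and most alternatives were fixed before the data were examined.

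The fit of shKdm5c#1 against control was tested on simulated data: of 50 genes each changed by 0.25, 0.5, 1 and 1.5 log2, it recovered 90 percent at 0.25 and 100 percent at the larger sizes, with 8 false calls among 203. Alternatives were the authors' values, no background correction, an offset of 16, median centring, quantile scaling of intensities between arrays, no dye term, each orientation alone, only the groups compared, array weights, a replicate block and a trended, robust empirical Bayes step. Others were the mean of a gene's probes, the dimmest 25 percent of probes left out (10294 of 41174), 19 probes never above background left out, a change of at least 1.5-fold, an estimated list correlation, each array left out in turn, and the IB10 reference as comparator. Probes without a symbol were fitted beside the others and counted only. Loess per print tip and slide or scan batches were not run, since the files mark no sub-arrays and no batch.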

Results

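Cy5 and Cy3 arrays compared 3 polyclonal lines of mouse IB10 embryonic stem cells, which carried a control hairpin, shKdm5c#1 or shKdm5c#2, with 4 cultures per line. Every culture was set against a common reference RNA of untreated IB10 cells, and 18322 genes were tested. Between 84.4 and 96.4 percent of gene spots per array stood above background in the sample channel. The 4 cultures per line limit the precision, with a median standard error of 0.04 log2 for a difference between lines. P-values measure the spread between cultures of 1 polyclonal line per hairpin, so they do not separate an effect of a hairpin from other differences between the lines. Gene values below are log2 differences with limma p-values adjusted by Benjamini-Hochberg over all genes, and list p-values are camera values adjusted over the 27 lists.

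Kdm5c, the X-linked H3K4 demethylase that both hairpins target, fell to 64.1 percent of the control level with shKdm5c#1 and to 61.7 percent with shKdm5c#2 by its brightest probe (log2 -0.64 and -0.70, standard error 0.05 for each, adjusted p = 1.66e-07 and 2.98e-08). Over the IB10 reference, cultures A to D read -0.57, -0.48, -0.75 and -0.69 with shKdm5c#1, -0.64, -0.67, -0.69 and -0.70 with shKdm5c#2, and 0.05, 0.04, 0.04 and -0.05 with the control hairpin. A dimmer probe, MMAB021192, put Kdm5c at 50.6 and 50.5 percent of control, with adjusted p-values over all probes of 7.65e-10 and 1.95e-10. A still dimmer probe, MMAB032660, gave -0.10 and -0.04 (adjusted p = 0.143 and 0.689). Kdm5c differed between the hairpins by 0.06 log2 (95 percent interval -0.05 to 0.16, adjusted p = 0.546). The paralogs Kdm5a and Kdm5b gave -0.17 and 0.02 with shKdm5c#1 (adjusted p = 0.0239 and 0.847) and 0.00 and -0.05 with shKdm5c#2 (adjusted p = 0.981 and 0.545). Among other H3K4 demethylases, Kdm1b fell by 0.34 and Kdm2b rose by 0.25 with shKdm5c#1 (adjusted p = 5.33e-05 and 9.28e-05), while Kdm2b fell by 0.13 with shKdm5c#2 (adjusted p = 0.0138). The fall of Kdm2b was not called with no dye term (adjusted p = 0.0546), in Cy5 alone (0.297) or in Cy3 alone (0.116). Its value stayed at -0.13 in each of these fits. Against IB10 it stood at -0.0026 (adjusted p = 0.960). The rise of Kdm2b with shKdm5c#1 was not called in Cy5 alone (adjusted p = 0.0592). Median centring in place of loess ended the calls of Kdm5a, Kdm1b and Kdm2b (-0.12, -0.29 and 0.30 with shKdm5c#1, adjusted p = 0.793, 0.386 and 0.300, and -0.08 for Kdm2b with shKdm5c#2, adjusted p = 0.858), and the mean of its probes put Kdm5a at -0.01 (adjusted p = 0.877).

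**Figure D1:**
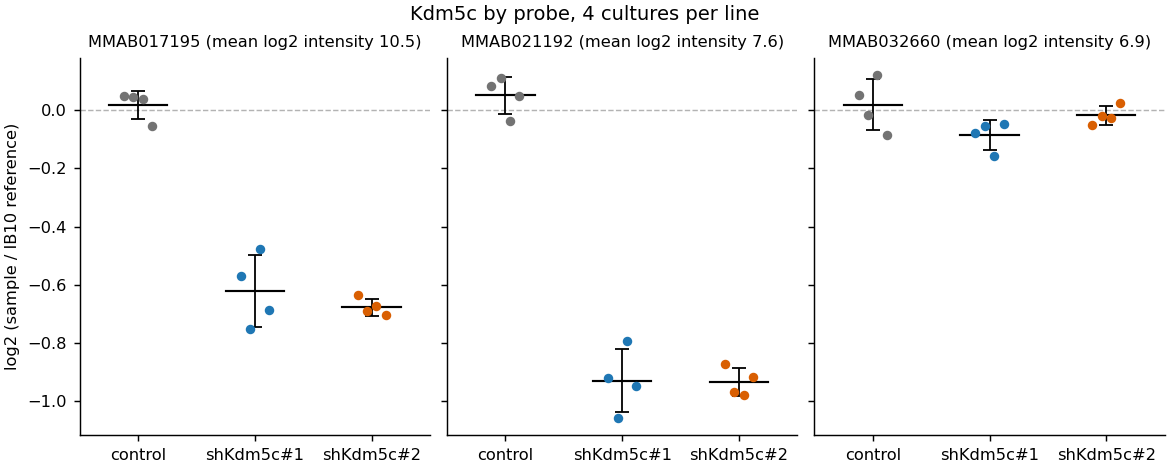
Kdm5c by probe in each culture: dye-adjusted log2 ratio of sample over IB10 reference (vertical axis) for the control, shKdm5c#1 and shKdm5c#2 lines, with points for the 4 cultures, a line at the mean and error bars of 1 SD. By the brightest probe the knockdown cultures sit between -0.75 and -0.48 and the control cultures between -0.05 and 0.05.

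With shKdm5c#1, 11 of 22 trophectoderm markers with the keratins among them, 13 of 39 interferon response genes and 21 of 41 genes of the unfolded protein and amino acid stress response rose against the control line, while 17 of 37 replication-dependent histone genes fell. With an estimated correlation the list tests of the stress response and the histones did not pass (adjusted p = 0.0735 and 0.0955). Krt18 and Krt8, keratin partners of simple epithelia, rose by 1.54 and 1.39 log2 (standard errors 0.04 and 0.05, adjusted p = 2.20e-12 and 1.25e-11, 4 cultures per line). T, the transcription factor brachyury of the primitive streak, rose 2.59-fold (log2 1.37, standard error 0.07, adjusted p = 7.87e-10). Atf4, a transcription factor of the amino acid stress response, and the stress-induced Nupr1 rose by 1.11 and 1.02 (adjusted p = 6.36e-12 and 6.43e-11). Srgn, a proteoglycan of secretory granules, and Cubn, an endocytic receptor of visceral endoderm, fell by 1.80 and 1.54 (adjusted p = 4.80e-13 and 4.86e-11). Smc1b, a meiotic cohesin subunit, rose by 1.16, and Cth, an enzyme of cysteine synthesis, by 1.08. Against IB10, a comparison chosen after the data were seen, T, Krt8 and Cubn were not called with shKdm5c#1 (-0.04, 0.09 and -0.03). Krt18, Atf4, Nupr1, Srgn, Smc1b and Cth kept a call of the same sign. The control line itself was lower than IB10 in 13 of 22 trophectoderm markers and 21 of 39 interferon response genes. In all, limma called 3419 genes against control, 1650 higher and 1769 lower, of which 94 differed by at least 1.5-fold (63 higher, 31 lower) and 13 by at least 2-fold.

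Among the fixed lists, 11 of 22 trophectoderm markers were higher with shKdm5c#1 and 0 lower (12 adjusted over the list alone, median 0.15, adjusted p = 9.88e-08, and 0.0155 with an estimated correlation). Among them were Krt7 at 0.63 and Lgals3 at 0.66. Of 39 interferon response genes, 13 were higher and 1 lower (15 over the list alone, adjusted p = 4.12e-05, and 0.0155 with an estimated correlation). Gbp2, an interferon-induced GTPase, and Psmb8, a subunit of the immunoproteasome, both stood at 0.81. These were the lists whose call held with an estimated correlation. Of 41 genes of the unfolded protein and amino acid stress response, 21 were higher and 6 lower (33 over the list alone, median 0.17, adjusted p = 1.71e-06, but adjusted p = 0.0735 with an estimated correlation). Trib3 and the arginine transporter Slc7a1 rose by 0.67 and 0.48. Of 37 replication-dependent histone genes, 17 were lower and 0 higher (17 over the list alone, median -0.10, adjusted p = 2.19e-08, but adjusted p = 0.0955 with an estimated correlation). The linker histone gene Hist1h1c stood at -1.03, Hist1h2bc at -0.89 and Hist3h2a at -0.60. Epiblast markers were higher for 9 of 19 members and lower for 2 (11 over the list alone, adjusted p = 0.00256, but adjusted p = 0.113 with an estimated correlation). The growth factor Fgf5 led at 0.87, before Cldn6 at 0.63 and Fst at 0.59. Of 31 extraembryonic endoderm markers, 13 were lower and 3 higher (16 over the list alone, adjusted p = 0.00256, but adjusted p = 0.0955 with an estimated correlation). The keratins Krt8 and Krt18 were among those that rose. Of 36 Hox genes, 5 were lower and 1 higher (5 over the list alone, adjusted p = 0.0394, but adjusted p = 0.0955 with an estimated correlation), with Hoxb2 at -0.59 and Hoxa10 at -0.38. The Hox call also ended without control B (adjusted p = 0.0713) or shKdm5c#1 D (0.0603) and without the dimmest 25 percent of probes (0.207).

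The other 20 lists were not called with shKdm5c#1. Fibroblast markers gave 5 higher and 11 lower of 31 (16 over the list alone, adjusted p = 0.161). The collagen genes Col1a1 and Col1a2 stood at -0.75 and -0.41. Germline genes gave 7 higher and 13 lower of 39 (25 over the list alone, adjusted p = 0.153), with the germ cell helicase Ddx4 at -0.61 and Tdrkh at -0.73. The 2-cell-stage genes gave 1 higher and 4 lower of 9 (6 over the list alone, adjusted p = 0.107). Mesoderm and primitive streak genes gave 8 higher and 3 lower of 30 (12 over the list alone, adjusted p = 0.0951), with Sp5 at 0.78, Wnt3 at 0.62 and Tcf15 at -0.69. Polycomb components gave 8 higher and 3 lower of 29 (11 over the list alone, adjusted p = 0.0797). Pluripotency factors gave 7 higher and 4 lower of 29 (12 over the list alone, adjusted p = 0.396), with Klf4 at -0.37 and Dppa3 at -0.38. FGF and ERK feedback targets gave 6 higher and 1 lower of 17 (12 over the list alone, adjusted p = 0.153), with Dusp4 at 0.54. LIF and Stat3 targets gave 4 higher and 5 lower of 18 (10 over the list alone, adjusted p = 0.759), and their median of 0.05 and mean of -0.02 differed in sign. Gbx2 among them stood at -0.58. Imprinted genes gave 6 higher and 13 lower of 38 (24 over the list alone, adjusted p = 0.257), with Grb10 at 0.93 and Mest at -0.84. Neuroectoderm genes gave 4 and 7 of 31 (13 over the list alone, adjusted p = 0.261), synaptic genes 2 and 2 of 31 (4, adjusted p = 0.850), p53 targets 6 and 2 of 32 (8, adjusted p = 0.335), and G2 and M phase genes 4 and 6 of 41 (11, adjusted p = 0.516), higher and lower in that order. S phase genes gave 8 higher and 3 lower of 46 (14 over the list alone, adjusted p = 0.472), where the median of -0.0024 and the mean of 0.02 differed in sign. Glycolysis genes gave 9 and 6 of 31 (17, adjusted p = 0.692), cholesterol synthesis 3 and 1 of 20 (4, adjusted p = 0.640), ribosomal proteins 2 and 7 of 54 (9, adjusted p = 0.461) and protocadherins 0 and 1 of 24 (1, adjusted p = 0.247). The H3K4 demethylases gave 1 higher and 3 lower of 8 (4, adjusted p = 0.388) and the H3K4 methyltransferase complexes 2 and 0 of 17 (2, adjusted p = 0.640). The gene count was 419 (249 higher) with median centring, which ended the calls of Klf4, Dppa3 and Dusp4 at values of -0.32, -0.33 and 0.55 (adjusted p = 0.249, 0.203 and 0.0701), 1944 without the dye term, 812 from the cultures in Cy5 alone and 1940 from those in Cy3 alone. Against the IB10 reference in place of the control, a comparison chosen after the data were seen, 44 of the 80 genes of the text that were called kept a call of the same sign, 17 were not called and 19 turned. Not called were Krt7, Krt8, T, Cubn, Hoxb2 and Mest (-0.03, 0.09, -0.04, -0.03, 0.02 and 0.02, lowest adjusted p 0.0665). Called with the other sign, Fgf5, Psmb8, Gbp2, Cldn6, Fst and Wnt3 turned to -0.27, -0.39, -0.27, -0.29, -0.19 and -0.11 and Gbx2, Klf4 and Hoxa10 to 0.40, 0.12 and 0.20 (highest adjusted p 0.00678).

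With shKdm5c#2, 12 of 19 markers of the primed epiblast, 18 of 39 interferon response genes and 10 of 30 mesoderm and primitive streak genes rose against the control line. Lower were 23 of 39 germline genes, 16 of 32 p53 targets, 15 of 31 extraembryonic endoderm markers and 12 of 31 fibroblast markers. T rose 4.19-fold (log2 2.07, standard error 0.07, adjusted p = 1.52e-12) and Fgf5, a growth factor of the epiblast, 3.82-fold (log2 1.93, standard error 0.06, adjusted p = 1.36e-12, 4 cultures per line). The kinase gene Pim2, Cyp26a1, which encodes a retinoic acid-degrading enzyme, and Otx2, a transcription factor of the primed epiblast, rose by 1.74, 1.63 and 1.26 (adjusted p = 1.69e-13, 9.83e-12 and 3.38e-12). Srgn and Cubn fell by 2.26 and 1.67 (adjusted p = 1.42e-14 and 3.97e-12), and Col1a1, a fibrillar collagen gene, by 1.46 (adjusted p = 5.03e-14). Against IB10 the genes named in this paragraph kept a call of the same sign. The control line itself was lower than IB10 in 12 of 19 epiblast markers, 21 of 39 interferon response genes and 12 of 30 mesoderm genes. Limma called 4074 genes against control, 1825 higher and 2249 lower, of which 187 differed by at least 1.5-fold (78 higher, 109 lower) and 43 by at least 2-fold.

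Of 19 epiblast markers, 12 were higher with shKdm5c#2 and 2 lower (14 over the list alone, median 0.32, adjusted p = 1.22e-11, and 0.00733 with an estimated correlation). They included the methyltransferase gene Dnmt3b at 1.02 and Fst at 1.18. Of 39 interferon response genes, 18 were higher and 1 lower (20 over the list alone, adjusted p = 2.32e-11, and 0.000910 with an estimated correlation). Psmb8 stood at 1.51, Gbp2 at 1.35 and Irf1 at 1.02. Of 30 mesoderm and primitive streak genes, 10 were higher and 6 lower (18 over the list alone, adjusted p = 0.00959, and 0.0433 with an estimated correlation). Sp5 and Wnt3 stood at 1.36 and 1.11, and Tcf15 at -0.67. Of 39 germline genes, 23 were lower and 6 higher (30 over the list alone, median -0.26, adjusted p = 4.14e-09, and 0.0124 with an estimated correlation). Rpl39l stood at -1.31, the piRNA pathway gene Mael at -1.25, Ddx4 at -1.09 and the synaptonemal complex gene Syce1 at -0.97. Of 32 p53 targets, 16 were lower and 1 higher (18 over the list alone, median -0.14, adjusted p = 2.42e-05, and 0.00733 with an estimated correlation). Gadd45a gave -0.65, Plk2 -0.58, Perp -0.55 and Mdm2 -0.48. Markers of other cell types fell beside them: 15 of 31 extraembryonic endoderm markers were lower and 2 higher (17 over the list alone, adjusted p = 2.42e-05, and 0.0262 with an estimated correlation), with Dab2 at -0.80. Of 31 fibroblast markers, 12 were lower and 4 higher (18 over the list alone, adjusted p = 0.000525, and 0.0433 with an estimated correlation). Col1a2 fell by 0.55, while Thy1 rose by 0.39. Trophectoderm markers gave 5 higher and 4 lower of 22 (10 over the list alone, adjusted p = 0.495), with Krt8 and Krt18 at 0.88 and 0.86 and the growth factor gene Igf2 at -0.89. The list's median of -0.01 and mean of 0.05 differed in sign.

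Further lists were called with shKdm5c#2 only under the preset correlation. Of 37 histone genes, 15 were lower and 0 higher (18 over the list alone, median -0.09, adjusted p = 2.42e-05, but adjusted p = 0.133 with an estimated correlation). Hist1h2bc stood at -1.40 and Hist1h1c at -1.13. Of 41 stress response genes, 16 were higher and 5 lower (22 over the list alone, adjusted p = 0.000703, but adjusted p = 0.105 with an estimated correlation). Atf4 and Psat1, an enzyme of serine synthesis, rose by 0.93 and 0.47, whereas Xbp1, a transcription factor of the unfolded protein response, fell by 0.58. Of 9 genes of the 2-cell stage, 5 were lower and 0 higher (5 over the list alone, median -0.33, adjusted p = 0.000222, but adjusted p = 0.0607 with an estimated correlation), with Zscan4c at -0.61. Hox genes gave 9 lower and 0 higher of 36 (9 over the list alone, adjusted p = 0.0209, but adjusted p = 0.0557 with an estimated correlation). Ribosomal protein genes gave 7 lower and 0 higher of 54 (4 over the list alone, adjusted p = 0.000941, but adjusted p = 0.473 with an estimated correlation). Rpl39l among them is the testis-enriched paralog that the germline list also holds. The H3K4 demethylases gave 2 lower, Kdm5c itself and Kdm2b, and 0 higher of 8 (3 over the list alone, adjusted p = 0.0464, but adjusted p = 0.112 with an estimated correlation). This call also ended without control A, C or D (adjusted p = 0.0594, 0.0531 and 0.0613) or shKdm5c#2 A or B (0.0630 and 0.0826). It ended with median centring (adjusted p = 0.305), no background correction (0.0509) and an offset of 16 (0.0538) as well. Without the dimmest 25 percent of probes the calls of demethylases and Hox genes ended (adjusted p = 0.0666 and 0.173), and with no dye term those of demethylases and ribosomal proteins (0.0505 and 0.0505).

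The lists not called with shKdm5c#2 included pluripotency factors, 5 higher and 9 lower of 29 (16 over the list alone, adjusted p = 0.209), although Tbx3, Klf4 and Nr0b1 of the naive network fell by 0.89, 0.72 and 0.70. LIF and Stat3 targets gave 3 higher and 7 lower of 18 (10 over the list alone, adjusted p = 0.0798), with Gbx2 at -0.96. FGF and ERK feedback targets gave 6 and 6 of 17 (12, adjusted p = 0.969) and imprinted genes 4 and 11 of 38 (15, adjusted p = 0.133), higher and lower in that order. In the same order, G2 and M phase genes gave 9 and 2 of 41 (15, adjusted p = 0.0954) and S phase genes 7 and 6 of 46 (13, adjusted p = 0.495). Neuroectoderm genes gave 7 and 7 of 31 (14, adjusted p = 0.813), with a median of 0.02 and a mean of -0.02, and synaptic genes 2 and 4 of 31 (6, adjusted p = 0.495). Glycolysis genes gave 10 and 7 of 31 (18, adjusted p = 0.233), cholesterol synthesis 4 and 2 of 20 (6, adjusted p = 0.382), protocadherins 0 and 1 of 24 (1, adjusted p = 0.495), Polycomb components 4 and 7 of 29 (12, adjusted p = 0.969) and H3K4 methyltransferase complexes 4 and 4 of 17 (11, adjusted p = 0.735). The gene count was 795 with median centring, which ended the calls of Thy1 and Psat1 at values of 0.25 and 0.47 (adjusted p = 0.546 and 0.158), 2607 without the dye term and 1298 from the cultures in Cy5 alone. Against the IB10 reference, 62 of the 80 called genes of the text kept a call of the same sign. Not called were 11, among them Gbx2 and Thy1 (0.03 and -0.02, adjusted p = 0.575 and 0.804), and 7 turned, among them Krt18 and Krt8 (-0.46 and -0.43, adjusted p = 1.06e-08 and 5.52e-08).

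**Figure D2:**
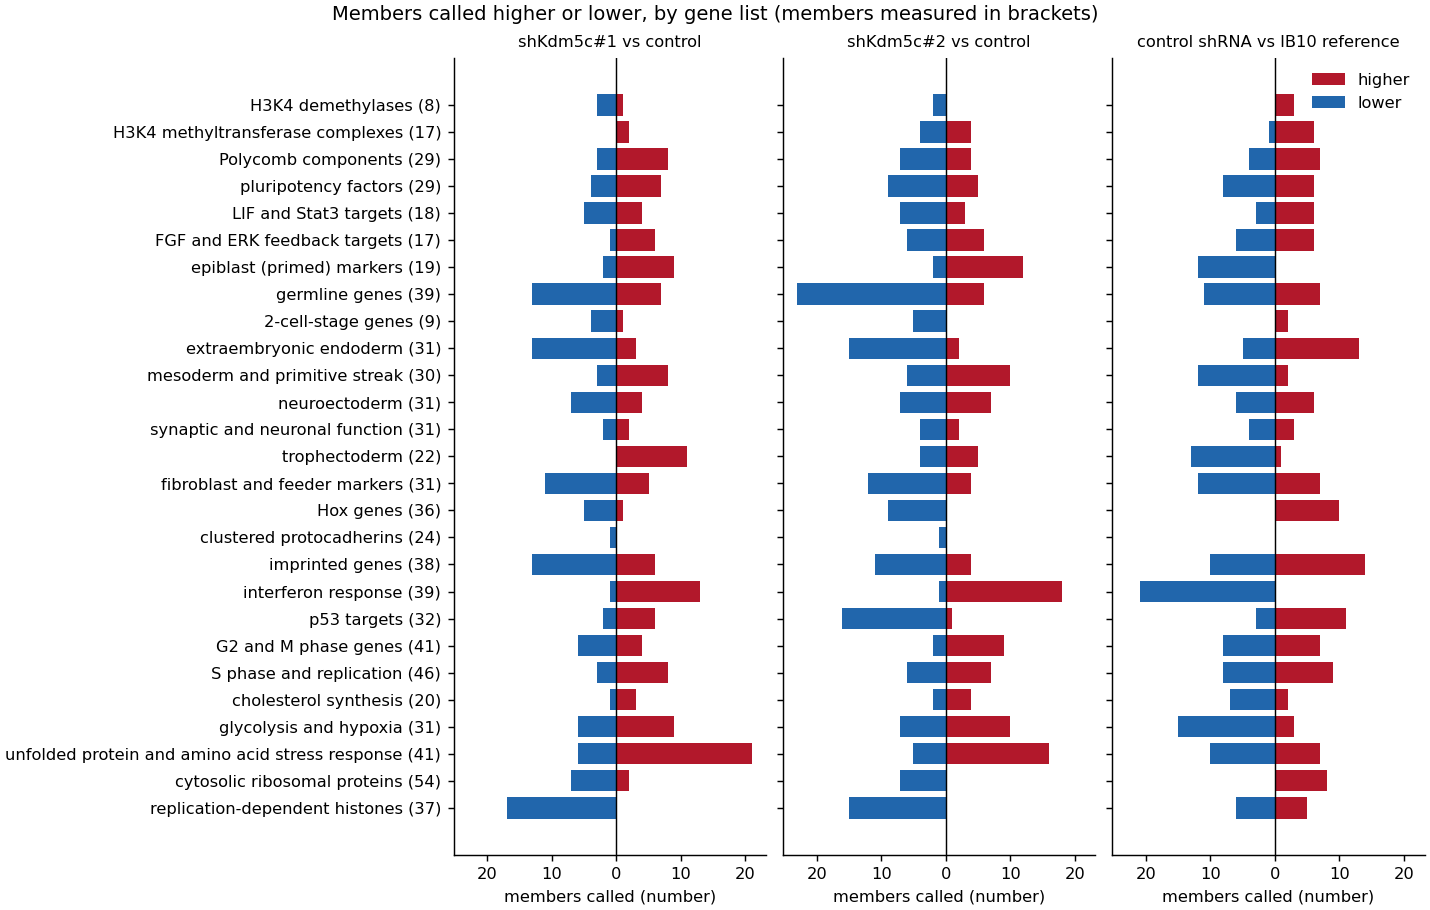
Number of members called higher (bars to the right) or lower (bars to the left) in each of the 27 gene lists, for shKdm5c#1 against control, shKdm5c#2 against control and control against the IB10 reference. Histone genes were lower for 17 and 15 members with the hairpins, and interferon response genes were higher for 13 and 18 members but lower for 21 in the control line against IB10.

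Both knockdown lines shared 1748 genes that changed in the same direction against control, 816 higher and 932 lower, and 47 of these changed by at least 1.5-fold in both (22 higher, 25 lower). Independent lists of these sizes would share 381, but both comparisons use the same control arrays of 1 line, so 381 is not their chance value. The highest mean changes belonged to T, Fgf5, Ppp4r4, Krt18 and Psmb8, and the lowest to Srgn, Cubn, Slc47a1, a multidrug transporter gene, Aard and Stra8, a retinoic acid-induced gene of meiotic entry. With shKdm5c#1 against IB10, Stra8 was not called (-0.0047, adjusted p = 0.934) and Aard turned to 0.46 (adjusted p = 7.43e-08). Among the fixed lists, 13 stress response genes were higher in both lines and 3 lower, with the aminoacyl-tRNA synthetase genes Aars, Cars, Gars and Nars among the 13 and the endoplasmic reticulum genes Hspa5, Dnajb9 and Xbp1 as the 3. The synthetase genes and Hspa5 were named after their values were seen. All 15 histone genes shared by both lines were lower. Of the germline genes, 13 were lower in both, among them Ddx4, Mael, Syce1 and Tdrkh, and 5 were higher, including Smc1b. Interferon response genes were higher in both for 12 and lower for 1, epiblast markers for 9 and 1, and mesoderm genes for 7 and 3. Of markers of other cell types, 13 extraembryonic endoderm and 8 fibroblast markers were lower in both, against 2 and 3 higher, and 4 trophectoderm markers were higher (Eomes, Krt8, Krt18 and Lgals3). A further 195 genes changed in opposite directions, 145 of them higher with shKdm5c#1 and lower with shKdm5c#2.

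Both comparisons use the same 4 control arrays, so chance values of the controls push them the same way. The log2 changes correlated at r = 0.596 across genes, against 0.501 in 20 simulations without effects, where at most 1 gene was called in both. The simulations held noise between cultures and no differences between lines, so few calls were bound to come of them. The covariance was 0.0118 against a simulated 0.000979. With the controls split between the comparisons, 1053 to 1102 genes were shared and r was 0.486 to 0.548. The split comparisons have no arrays in common, so the simulated 0.501 is not their chance value. Their control arrays still come from 1 control line. The control line itself lay apart from IB10: for 1246 of the 1748 genes it differed from the reference in the direction opposite to the shared change, and 651 genes differed from IB10 in both knockdown lines in that shared direction. Of the 47 genes past 1.5-fold in both, the control line lay opposite to the change for 44, and 27 also differed from IB10 in both lines, 8 of the 22 higher and 19 of the 25 lower. Set against IB10, 4 of 5 higher and 13 of 13 lower germline genes, 11 of 13 higher and 2 of 3 lower stress response genes and 12 of 15 lower histone genes kept their shared call. By the same measure 0 of 9 higher epiblast markers, 2 of 12 higher interferon response genes, 2 of 7 higher mesoderm genes and 0 of 4 higher trophectoderm markers did so. Among lower genes these were 1 of 1 epiblast marker, 1 of 1 interferon response gene, 3 of 3 mesoderm genes, 6 of 13 extraembryonic endoderm markers, 3 of 8 fibroblast markers and 0 of 5 Hox genes. Genes in which 1 line alone differed the same way from both others numbered 1748 for the control, 1190 for shKdm5c#1 and 1807 for shKdm5c#2. The shared count was 236 with median centring, which ended the call of Aard with shKdm5c#1 at a value of -0.42 (adjusted p = 0.113), 977 without the dye term, 435 from the cultures in Cy5 alone and 905 from those in Cy3 alone.

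**Figure D3:**
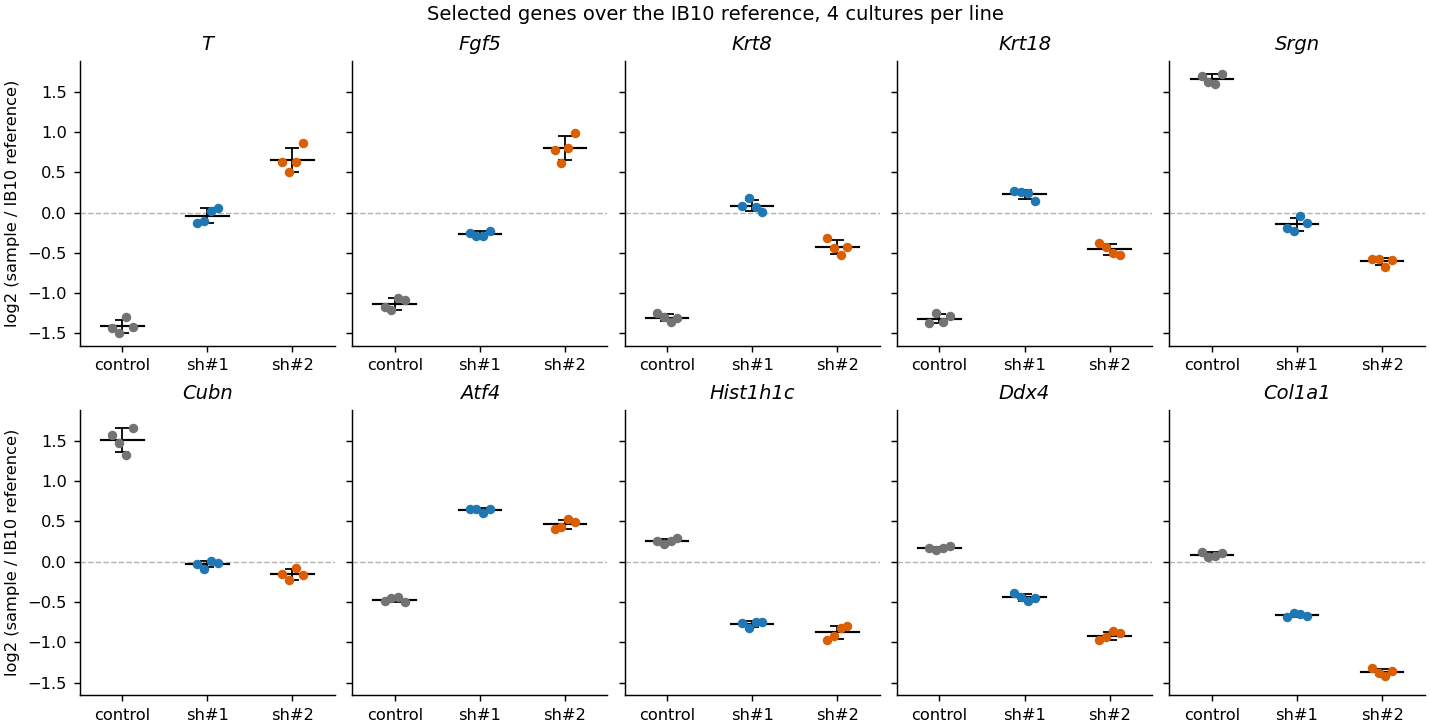
Dye-adjusted log2 ratio of sample over IB10 reference (vertical axis) of 10 genes in the control, shKdm5c#1 and shKdm5c#2 lines, with points for the 4 cultures of each line, a line at the mean and error bars of 1 SD. T, Fgf5, Krt8 and Krt18 lay below the reference in the control line at -1.41, -1.13, -1.30 and -1.32, while Hist1h1c lay below it in the knockdown lines at -0.77 and -0.88.

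The mean of both knockdown lines differed from control in 3941 genes, 1785 higher and 2156 lower, and 101 of these differed by at least 1.5-fold (49 higher, 52 lower). Kdm5c stood at 62.9 percent of control in this comparison. Interferon response genes were higher for 19 of 39 members and lower for 1 (22 over the list alone, adjusted p = 1.77e-09, and 0.00159 with an estimated correlation), epiblast markers for 11 and 1 of 19 (12, adjusted p = 6.95e-09, and 0.0225). Stress response genes were higher for 21 and lower for 5 of 41 (35 over the list alone, adjusted p = 3.24e-06, and 0.0485 with an estimated correlation). Mesoderm and primitive streak genes were higher for 11 and lower for 5 of 30 (16 over the list alone, adjusted p = 0.0118, and 0.0485 with an estimated correlation). Germline genes were lower for 19 and higher for 5 of 39 (25 over the list alone, adjusted p = 5.42e-06, and 0.0485 with an estimated correlation), extraembryonic endoderm markers for 15 and 3 of 31 (18, adjusted p = 9.36e-05, and 0.0485), and Hox genes for 10 and 0 of 36 (11, adjusted p = 0.0126, and 0.0485). Called under the preset correlation alone were histones (17 lower and 0 higher of 37, 17 over the list alone, adjusted p = 1.21e-07, but adjusted p = 0.0727 with an estimated correlation). The 2-cell-stage genes followed (5 lower and 0 higher of 9, 6 over the list alone, adjusted p = 0.00198, but adjusted p = 0.0838 with an estimated correlation). So were fibroblast markers (11 lower and 5 higher of 31, 20 over the list alone, adjusted p = 0.00658, but adjusted p = 0.0703 with an estimated correlation), p53 targets (9 and 3 of 32, 14, adjusted p = 0.0184, but 0.0580) and ribosomal proteins (9 and 0 of 54, 8, adjusted p = 0.0109, but 0.523). Trophectoderm markers were higher for 7 and lower for 3 of 22 (13 over the list alone, adjusted p = 0.00215, but adjusted p = 0.0588 with an estimated correlation). The other 14 lists were not called (adjusted p = 0.109 to 0.782). The p53 call ended without control B (adjusted p = 0.0598), that of ribosomal proteins without shKdm5c#2 C or control C or D (0.0503, 0.0698 and 0.0640) or with no dye term (0.0871), those of mesoderm genes, p53 targets and ribosomal proteins with median centring (0.0690, 0.398 and 0.174) and that of Hox genes without the dimmest 25 percent of probes (0.150). The gene count was 687 with median centring, 2356 without the dye term, 1142 from the cultures in Cy5 alone and 2378 from those in Cy3 alone.

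The knockdown lines also differed from each other, with 12 of 19 epiblast markers and 16 of 39 interferon response genes lower, and 18 of 39 germline genes, 16 of 32 p53 targets and 12 of 22 trophectoderm markers higher, in shKdm5c#1 than in shKdm5c#2. Pim2, Fgf5 and Otx2 were lower by log2 differences of -1.27, -1.06 and -1.05 (standard errors 0.04, 0.06 and 0.04, adjusted p = 1.15e-11, 3.26e-09 and 8.69e-11, 4 cultures per line). Rpl39l, Mael and Dazl, an RNA-binding protein gene of germ cells, were higher by 1.55, 1.06 and 1.04 (adjusted p = 7.07e-13, 7.26e-11 and 2.55e-09). Tbx3, a transcription factor of the naive pluripotency network, was higher by 1.07 and Igf2 by 1.09, whereas Dppa3 and Pttg1, which encodes securin, gave -0.77 and -1.30. Limma called 3404 genes, 1844 higher and 1560 lower in shKdm5c#1, of which 112 differed by at least 1.5-fold (86 higher, 26 lower).

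Epiblast markers were lower for 12 of 19 members and higher for 1 (14 over the list alone, adjusted p = 1.11e-12, and 0.00436 with an estimated correlation), with Dnmt3b at -0.72. Interferon response genes gave 16 lower and 1 higher of 39 (19 over the list alone, adjusted p = 2.42e-07, and 0.00261 with an estimated correlation), with Psmb8 at -0.70, Irf1 at -0.69 and the class I antigen gene H2-K1 at -0.54. Germline genes gave 18 higher and 3 lower of 39 (22 over the list alone, adjusted p = 1.32e-09, and 0.00991 with an estimated correlation), p53 targets 16 and 1 of 32 (19 over the list alone, adjusted p = 9.09e-08, and 0.00261), with Perp at 0.62, and trophectoderm markers 12 and 1 of 22 (13 over the list alone, adjusted p = 6.35e-07, and 0.0106), with Krt7 at 0.66. Under the preset correlation alone, pluripotency factors (10 higher and 4 lower of 29, 15 over the list alone, adjusted p = 0.00503, but adjusted p = 0.106 with an estimated correlation) and LIF and Stat3 targets (6 and 1 of 18, 7 over the list alone, adjusted p = 0.0199, but adjusted p = 0.0696 with an estimated correlation) were higher. So were 2-cell-stage genes (5 and 0 of 9, 6 over the list alone, adjusted p = 0.000385, but adjusted p = 0.0696 with an estimated correlation) and ribosomal proteins (7 and 3 of 54, 10 over the list alone, adjusted p = 0.0298, but adjusted p = 0.681 with an estimated correlation). Extraembryonic endoderm markers (10 and 1 of 31, 11 over the list alone, adjusted p = 0.000385, but adjusted p = 0.0502 with an estimated correlation) and fibroblast markers (10 and 3 of 31, 13 over the list alone, adjusted p = 0.0159, but adjusted p = 0.106 with an estimated correlation) were higher beside them. Mesoderm genes (3 higher and 8 lower of 30, 13 over the list alone, adjusted p = 0.0298, but adjusted p = 0.0696 with an estimated correlation) and G2 and M phase genes (1 and 15 of 41, 17 over the list alone, adjusted p = 0.0136, but adjusted p = 0.217 with an estimated correlation) were lower. Without shKdm5c#2 D the calls of mesoderm genes, fibroblast markers and ribosomal proteins ended (adjusted p = 0.0569, 0.0508 and 0.111), as did that of ribosomal proteins without shKdm5c#1 C or D or shKdm5c#2 C (0.0867, 0.197 and 0.251). The ribosomal call ended with no background correction (adjusted p = 0.0576), the authors' values (0.134) and no dye term (0.237) too, and that of G2 and M phase genes with median centring (0.0605). The gene count was 474 (339 higher) with median centring, 2007 without the dye term, 741 from the cultures in Cy5 alone and 2256 from those in Cy3 alone.

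**Figure D4:**
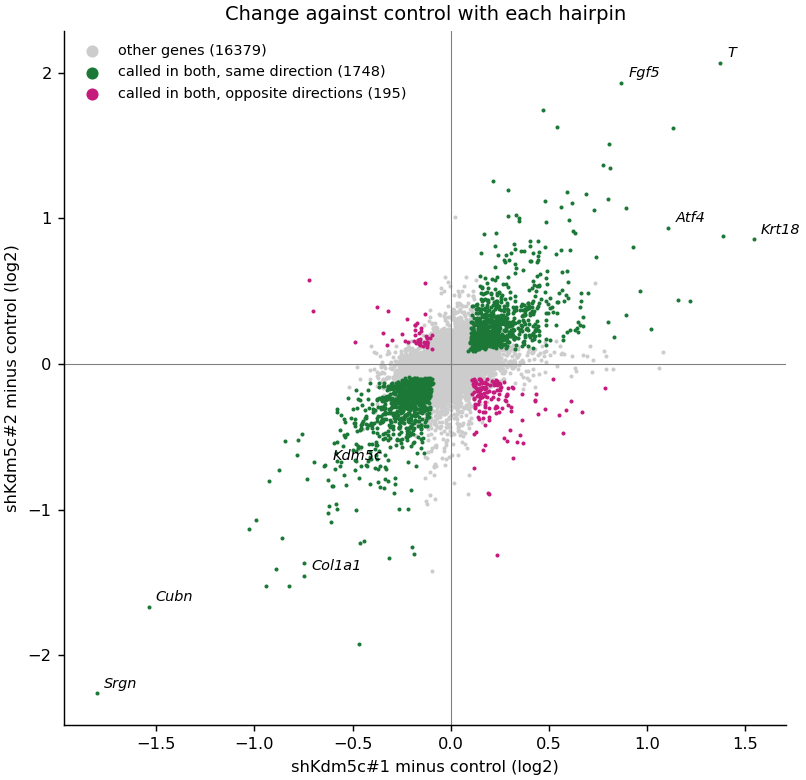
Log2 change against control with shKdm5c#1 (horizontal axis) and shKdm5c#2 (vertical axis) for the 18322 genes, where each point is a gene. Colours mark the 1748 genes called in both in the same direction and the 195 called in opposite directions.

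The control line differed from the IB10 reference in genes named above for the knockdown lines, with 21 of 39 interferon response genes, 12 of 19 epiblast markers, 12 of 30 mesoderm and primitive streak genes and the keratins lower and 10 of 36 Hox genes higher. T and Fgf5 gave -1.41 and -1.13 (standard errors 0.05 and 0.04, adjusted p = 2.83e-12 and 9.07e-12), Krt18 and Krt8 -1.32 and -1.30, and Psmb8 and Gbp2 -1.20 and -1.08, with 4 control cultures. Srgn and Cubn were higher by 1.66 and 1.51 (adjusted p = 8.21e-15 and 2.78e-13), followed by Plagl1, an imprinted zinc finger gene, at 1.35 and Gbx2, a LIF target, at 0.99. Limma called 4816 genes, 2308 higher and 2508 lower, of which 92 differed by at least 1.5-fold (23 higher, 69 lower). Per the labels the reference was a common IB10 RNA, taken here as 1 preparation. Its own spread is left out of this test and of the tests of the knockdown lines against IB10.

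Interferon response genes were lower for 21 of 39 members and higher for 0 (21 over the list alone, adjusted p = 4.31e-12, and 0.000657 with an estimated correlation), epiblast markers for 12 and 0 of 19 (12 over the list alone, adjusted p = 7.73e-11, and 0.0118) and mesoderm and primitive streak genes for 12 and 2 of 30 (17 over the list alone, adjusted p = 0.000909, and 0.0157). Trophectoderm markers gave 13 lower and 1 higher of 22 (16 over the list alone, adjusted p = 1.37e-07, and 0.0118 with an estimated correlation), and Hox genes 10 higher and 0 lower of 36 (12 over the list alone, adjusted p = 0.000909, and 0.0157), with Hoxb2 at 0.61 and Hoxa10 at 0.58. Extraembryonic endoderm markers gave 13 higher and 5 lower of 31 (19 over the list alone, adjusted p = 0.00163, but adjusted p = 0.0801 with an estimated correlation). Glycolysis genes gave 15 lower and 3 higher of 31 (19 over the list alone, adjusted p = 0.000284, but adjusted p = 0.149 with an estimated correlation), with Bnip3 at -0.58 and Tpi1 at -0.38. The p53 targets gave 11 higher and 3 lower of 32 (15 over the list alone, adjusted p = 0.0381, but adjusted p = 0.0825 with an estimated correlation) and ribosomal proteins 8 and 0 of 54 (8 over the list alone, adjusted p = 0.0228, but adjusted p = 0.639 with an estimated correlation). The p53 call ended without control B (adjusted p = 0.170), with median centring (0.458) and with no dye term (0.0985). That of ribosomal proteins ended without control C or D (adjusted p = 0.198 and 0.141), with median centring (0.0608), with the authors' values (0.0787) and with no dye term (0.110). Histone genes gave 5 higher and 6 lower of 37 (11 over the list alone, adjusted p = 0.725), with a median of -0.0073 and a mean of 0.02, and fibroblast markers 7 and 12 of 31 (21 over the list alone, adjusted p = 0.231). The gene count was 988 (346 higher) with median centring, 3164 without the dye term and 2741 from the cultures in Cy5 alone.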

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

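The tests of divergence of the control line alone, of unequal knockdown and of the S-phase share were chosen after the results were seen, as was the comparison with IB10 in place of the control, while no background correction and median centring in the histone test were added after the data were seen but before that test was run.

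Of the 1748 genes changed in both knockdowns, 1246 differed from IB10 in the control line in the direction opposite to the shared change. T, Fgf5, Krt8 and Krt18 were among them. This measure did not require the knockdown lines to lie on the other side of IB10. Chance values of the shared control arrays and dye bias of these arrays are both argued against: with part of the controls held out, at least 87.2 percent of genes kept the opposite side in held-out cultures, and 88.3 percent when the held-out cultures were of the other dye orientation, where chance gives about 50 percent. Divergence of the control line alone is argued against for 226 of these genes, which also differed from IB10 in both knockdown lines in the direction of their change. They were picked by those calls, and lines that each diverged from IB10 could give such genes too. Both calls also rest on the same IB10 RNA, whose own spread is left out, so they are not independent. The argument holds only as far as this RNA stood for IB10 cells. Of 18322 genes, 4958 and 4810 were called against IB10 with shKdm5c#1 and shKdm5c#2. For the other 1020 genes, divergence of the control line alone cannot be told apart from an effect of the hairpins, because leaving out the 226 fixes that outcome. Neither knockdown line was called against IB10 for 359 of them. Independent divergence of the 3 polyclonal lines may account for the pattern, in part or as a whole. By the same measure, 1807 genes set shKdm5c#2 alone apart from the other lines and 1190 set shKdm5c#1 alone apart, against 1748 for the control. The biological explanation, loss of Kdm5c, stays open beside it, with 1 polyclonal line per hairpin and no line in which Kdm5c was restored.

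The hairpins differed from each other in 3404 genes, while Kdm5c stood at 64.1 and 61.7 percent of control by the brightest probe. Unequal knockdown of Kdm5c is argued against for 47 genes, which passed a joint test over all 18322 genes that 1 hairpin raised and the other lowered them, unless their response turned with the level of Kdm5c. For the other differing genes it cannot be told apart from other causes, since the Kdm5c difference of 0.055 log2 has a 95 percent interval of -0.05 to 0.16. Targets other than Kdm5c and differences between the polyclonal lines were not tested and stay open.

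Genes of the list of replication-dependent histones, picked by symbol alone, were lower with both hairpins, 15 of them in both lines. The normalization is argued against as the cause, with camera adjusted p-values of at most 4.41e-05 in both comparisons under the authors' values, median centring and no background correction, although the call was lost with an estimated correlation (adjusted p = 0.0955 and 0.133). A lower share of S-phase cells cannot be told apart from other causes, because the S phase list had a median of 0.018 in the mean of both knockdowns, with members on either side of 0. No other biological explanation was tested, and loss of Kdm5c and differences between the lines stay open.

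Chance assignment of single cultures to groups is argued against for the gene counts of the comparisons between lines, while control against IB10 was not split. The other assignments mix cultures of different lines, which adds line differences to the spread and lowers their counts. With 1 polyclonal line per hairpin, they cannot test chance differences between the lines. The 35 splits and 100 assignments also limit how rare a count can be shown to be. Of 35 splits of the 8 arrays, only the real 1 reached its count for shKdm5c#1 (3419, highest other split 0), shKdm5c#2 (4074, highest other 3) and shKdm5c#1 against shKdm5c#2 (3404, highest other 1). Among 100 assignments of the 12 arrays, only the real 1 did so for the mean of both knockdowns (3941, highest other 154) and for genes changed in both (1748, highest other 0).

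For each of the 87 genes named, the cultures of each line were searched for 1 that lay far from the other 3. Chance gives about 1 in 20 groups, and 9 of 261 groups tested had such a culture. Culture D of the control read -0.052 for Kdm5c, where the others read 0.04 to 0.05, and -0.22 for Nupr1 (others -0.12 to -0.10). Culture C of shKdm5c#1 read 0.60 for Atf4 (others 0.65), and culture A read -0.063 for Hspa5 (others -0.18 to -0.17) and -0.35 for P4ha2 (others -0.40). Culture A of the control read -0.10 for Hspa5, where the others read 0.11 to 0.14. In shKdm5c#2, culture C read -0.67 for Srgn (others -0.59 to -0.58), and culture D read 0.44 for Psmb8 (others 0.26 to 0.27) and 0.54 for Psat1 (others 0.40 to 0.41). In all 80 calls per hairpin among these genes, the 4 knockdown cultures lay on the side of the change from the control mean. The calls were made on these same cultures, so this outcome was likely from the choice of genes.

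By limma's test of the difference itself, 67 of the 87 named genes differed between the hairpins, given here as shKdm5c#1 minus shKdm5c#2 in log2. Over all genes 3404 of 18322 did so. The naming rule takes genes by their values in this comparison among others, which raises the share among named genes. Higher with shKdm5c#1 by over 1 log2 were Rpl39l (1.55), Aard (1.45), Igf2 (1.09), Tbx3 (1.07), Mael (1.06) and Dazl (1.04). By 0.6 to 1 log2, the higher genes were Cth (1.00), Nupr1 (0.78), Smc1b (0.72), Col1a1 (0.71), Stra8 (0.70), Krt18 (0.69), Krt7 (0.66), Nr0b1 (0.63), Perp (0.62), Trib3 (0.62) and Gadd45a (0.60). Smaller positive differences were those of Slc47a1 (0.58), Mdm2 (0.55), Plk2 (0.54), Slc7a1 (0.53), Neurod1 (0.52), Hist1h2bc (0.52), Krt8 (0.51), Ddx4 (0.48), Srgn (0.46), Zscan4c (0.44), Gbx2 (0.38), Kdm2b (0.37), Syce1 (0.35), Klf4 (0.35), Lgals3 (0.27), Nefh (0.24), Hist3h2a (0.23), Hoxa10 (0.20), Atf4 (0.17), Dab2 (0.17), Ndrg1 (0.14), Col1a2 (0.13), P4ha2 (0.13) and Grb10 (0.13). Lower with shKdm5c#1 by over 0.6 log2 were Pttg1 (-1.30), Pim2 (-1.27), Cyp26a1 (-1.09), Fgf5 (-1.06), Otx2 (-1.05), Dppa3 (-0.77), Dnmt3b (-0.72), Psmb8 (-0.70), T (-0.69) and Irf1 (-0.69). Smaller negative differences were those of Sp5 (-0.59), Fst (-0.59), H2-K1 (-0.54), Gbp2 (-0.53), Wnt3 (-0.49), Ppp4r4 (-0.49), Eomes (-0.46), Bnip3 (-0.44), Nefl (-0.44), Mest (-0.32), Tpi1 (-0.27), Cldn6 (-0.26), Pax6 (-0.25), Kdm1b (-0.22), Kdm5a (-0.17) and Psat1 (-0.14). Median centring ended 10 of these calls, with values of 0.38 for Kdm2b (adjusted p = 0.134), 0.35 for Klf4 (0.172), 0.38 for Gbx2 (0.0712), 0.26 for Nefh (0.799), 0.24 for Hist3h2a (0.0999), 0.20 for Hoxa10 (0.297), -0.43 for Nefl (0.146), -0.29 for Mest (0.712), -0.22 for Kdm1b (0.708) and -0.17 for Kdm5a (0.568). Arrays with the sample in Cy5 alone also ended those of Nefh (adjusted p = 0.306), Hist3h2a (0.170), Hoxa10 (0.354), Mest (0.0598), Kdm1b (0.341) and Kdm5a (0.382). The Kdm5a call was further lost with the mean of its probes (-0.02, adjusted p = 0.726), no dye term (0.165), Cy3 alone (0.0700), and without shKdm5c#1 A (0.0744) or B (0.0531) or shKdm5c#2 B (0.0629) or C (0.0876).

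Camera called a difference between the hairpins for 13 of the 27 lists: pluripotency factors (adjusted p = 0.00503), LIF and Stat3 targets (adjusted p = 0.0199), epiblast (primed) markers (adjusted p = 1.11e-12), germline genes (adjusted p = 1.32e-09), 2-cell-stage genes (adjusted p = 0.000385), extraembryonic endoderm (adjusted p = 0.000385), mesoderm and primitive streak (adjusted p = 0.0298), trophectoderm (adjusted p = 6.35e-07), fibroblast and feeder markers (adjusted p = 0.0159), interferon response (adjusted p = 2.42e-07), p53 targets (adjusted p = 9.09e-08), G2 and M phase genes (adjusted p = 0.0136) and cytosolic ribosomal proteins (adjusted p = 0.0298). Of these, 5 kept the call with an estimated correlation. Among the 6988 probes without a symbol, 189 were called in both knockdowns in the same direction.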

How the results depend on the processing

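The IB10 reference as comparator, and lists under no background correction, an offset of 16 and median centring, were alternatives chosen after the data were seen, the last of these and no background correction before the histone test that uses them was run. Kdm5c kept its direction and its call for both hairpins under every alternative run (-0.57 to -0.72 log2). Over the 6 gene counts, 142 of 170 values stayed within 1.5 times of the main count. Over 135 list results, 2887 of 2970 values kept their side of the threshold and 0 reversed, while 71 lost a call and 12 gained a call. Lists called neither in the main fit nor in the alternative count as kept and cannot reverse. The 2887 therefore do not measure how many list calls held. Over 530 gene results 13733 of 14236 values kept their side of the threshold, with 9 of the other sign, all against IB10, which was run there for part of the genes only. These results cover only genes called in the main fit and picked for large changes or small p-values. Most were therefore likely to keep their call, and the 13733 do not measure how calls of other genes held. Where a call ended, the cause was not tested, with the exceptions that follow. A fold minimum lowers a count by construction. Each line had as many arrays in Cy5 as in Cy3, so leaving out the dye term kept the estimates and moved dye effects into the residual. Fits of 1 orientation used fewer arrays, which lowers power. Calls lost in these fits therefore do not by themselves speak against an effect. Signal over background limits the dimmest probes: without the dimmest 25 percent, 16213 genes were tested and each gene count stayed within 1.5 times. Loess per print tip was not run because the files mark no sub-arrays, and a slide or scan batch was not run because none is given.

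Gene counts follow for shKdm5c#1, shKdm5c#2, shKdm5c#1 against shKdm5c#2, the mean of both knockdowns, control against IB10, and genes changed in both. A change of at least 1.5-fold gave 94, 187, 112, 101, 92 and 47. Median centring gave 419, 795, 474, 687, 988 and 236, and no dye term 1944, 2607, 2007, 2356, 3164 and 977. Arrays with the sample in Cy5 gave 812, 1298, 741, 1142, 2741 and 435. Arrays with the sample in Cy3 gave 1940 for shKdm5c#1, 2256 between the hairpins, 2378 for the mean and 905 in both. With 1 array left out, counts were 2791 to 4173, 3410 to 4317, 2759 to 4012, 3106 to 4385, 3485 to 5504 and 1407 to 1918. Without culture D of shKdm5c#2, the array with the largest residual SD (0.08 log2), they rose to 4173, 4317, 4012, 4385, 5504 and 1918.

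Against IB10 in place of the control, 4958 and 4810 genes were called and 1995 in both. Among the Kdm5c level and the genes named as highest or lowest in both knockdowns, the sign turned with shKdm5c#1 for Fgf5 (-0.27), Psmb8 (-0.39), Pim2 (-0.82), Gbp2 (-0.27) and Aard (0.46), and with shKdm5c#2 for Krt18 (-0.46) and Krt8 (-0.43), all called against IB10 (highest adjusted p 0.000165). With shKdm5c#1, T (-0.040, adjusted p = 0.605) and Cyp26a1 (-0.035, adjusted p = 0.626) took the other sign but were not called against IB10. Over all 87 genes named, 19 turned and were called with shKdm5c#1 and 7 with shKdm5c#2, and 17 and 11 were not called. Among the genes named in the text, median centring ended 47 calls, arrays with the sample in Cy5 alone 18, arrays in Cy3 alone 4 and no dye term 4. The Kdm5a call with shKdm5c#1 was lost without shKdm5c#1 A (adjusted p = 0.0788), shKdm5c#1 B (0.0585), control C (0.0707) or control D (0.0902), and that of Kdm2b with shKdm5c#2 without shKdm5c#2 B (0.0519).

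The values below are camera adjusted p-values. With an estimated correlation, calls were lost for shKdm5c#1 in epiblast markers (0.113), extraembryonic endoderm (0.0955), Hox genes (0.0955), the stress response (0.0735) and histones (0.0955). For shKdm5c#2 these were H3K4 demethylases (0.112), 2-cell-stage genes (0.0607), Hox genes (0.0557), the stress response (0.105), ribosomal proteins (0.473) and histones (0.133). Between the hairpins they were pluripotency factors (0.106), LIF targets (0.0696), 2-cell-stage genes (0.0696), extraembryonic endoderm (0.0502), mesoderm (0.0696), fibroblast markers (0.106), G2 and M phase genes (0.217) and ribosomal proteins (0.681). For control against IB10 they were extraembryonic endoderm (0.0801), p53 targets (0.0825), glycolysis (0.149) and ribosomal proteins (0.639). For the mean of both knockdowns they were 2-cell-stage genes (0.0838), trophectoderm (0.0588), fibroblast markers (0.0703), p53 targets (0.0580), ribosomal proteins (0.523) and histones (0.0727).

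Median centring brought calls for shKdm5c#1 in Polycomb components (0.0215), FGF targets (0.0281), 2-cell-stage genes (0.00687) and fibroblast markers (0.0215), for shKdm5c#2 in G2 and M phase genes (0.0298), and between the hairpins in neuroectoderm (0.0125) and the stress response (0.0178). It ended those of H3K4 demethylases with shKdm5c#2 (0.305), of G2 and M phase genes between the hairpins (0.0605), of p53 targets (0.458) and ribosomal proteins (0.0608) in control against IB10, and of mesoderm (0.0690), p53 targets (0.398) and ribosomal proteins (0.174) in the mean of both knockdowns. The shKdm5c#2 call of H3K4 demethylases also ended with no background correction (0.0509), an offset of 16 (0.0538), the dimmest 25 percent left out (0.0666) and no dye term (0.0505). Ribosomal proteins lost their call between the hairpins with no background correction (0.0576), the authors' values (0.134) and no dye term (0.237). They also lost it in control against IB10 with the authors' values (0.0787) and no dye term (0.110), and with shKdm5c#2 with no dye term (0.0505). Without the dimmest 25 percent, Hox genes lost theirs with shKdm5c#1 (0.207), shKdm5c#2 (0.173) and in the mean (0.150). Without a dye term so did p53 targets in control against IB10 (0.0985) and ribosomal proteins in the mean (0.0871).

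Leaving out 1 array in turn changed these list calls, given with the lowest and highest adjusted p. For shKdm5c#1, Polycomb components (0.0458 to 0.142) passed without control B, 2-cell-stage genes (0.0358 to 0.162) passed without shKdm5c#1 C, and Hox genes (0.0256 to 0.0713) failed without shKdm5c#1 D (0.0603) or control B (0.0713). For shKdm5c#2, H3K4 demethylases (0.0335 to 0.0826) failed without shKdm5c#2 A (0.0630) or B (0.0826) or control A (0.0594), C (0.0531) or D (0.0613). LIF targets (0.0405 to 0.107) passed without shKdm5c#2 D, and G2 and M phase genes (0.0285 to 0.183) without shKdm5c#2 A. Between the hairpins, mesoderm genes (0.0187 to 0.0569) and fibroblast markers (0.00874 to 0.0508) failed without shKdm5c#2 D, and the stress response (0.0326 to 0.234) passed without shKdm5c#2 B. Ribosomal proteins there (0.00240 to 0.251) failed without shKdm5c#1 C (0.0867) or D (0.197) or shKdm5c#2 C (0.251) or D (0.111). In control against IB10, p53 targets (0.0241 to 0.170) failed without control B, and ribosomal proteins (0.000841 to 0.198) failed without control C (0.198) or D (0.141). In the mean of both knockdowns, p53 targets (0.0129 to 0.0598) failed without control B, and ribosomal proteins (0.000385 to 0.0698) without control C (0.0698) or D (0.0640) or shKdm5c#2 C (0.0503).

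With the culture letter as a replicate block, counts were 3837, 4520, 3753, 4414, 5192 and 1989. All were above the main counts. The letters were not taken to pair the cultures, by a rule that asked for a correlation over 0.1 in every same-letter pair. Residuals of arrays with the same letter correlated at -0.28 to 0.28, with 4 of 12 pairs over 0.1, and 3 of 12 arrays correlated best with their own letter. Arrays of the same letter share a dye orientation, and removing the dye term by itself lowers the correlation of their residuals. The rule and the count of best matches therefore lean against pairing. Pairs of letters B and D were all positive and those of A and C all negative, so an effect of the letter is not ruled out.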

Other observations

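The comparisons with IB10 in this part were chosen after the results were seen. Among neural genes, Neurod1 and Pax6, transcription factors of neuronal and neuroectoderm development, fell in both knockdown lines against control, by 0.48 and 0.58 log2 with shKdm5c#1 and by 1.01 and 0.33 with shKdm5c#2 (4 cultures per line, all of them below the control mean). Against IB10, Pax6 was not called with shKdm5c#1 (0.0091, adjusted p = 0.868) and lay higher with shKdm5c#2 (0.26, adjusted p = 3.58e-06), and the control line stood 0.59 above IB10. The neurofilament genes parted: Nefh fell by 0.46 and 0.70, and Nefl rose by 0.27 and 0.71. Of the neuroectoderm list 7 genes were lower in both lines and 3 higher, 3 of the 7 and 0 of the 3 kept their call against IB10, and the list was called with neither hairpin. For shKdm5c#1 the calls of Nefh and Nefl were lost against IB10 (-0.08 and -0.03, adjusted p = 0.106 and 0.555) and with median centring at values of -0.41 and 0.33 (adjusted p = 0.359 and 0.358).

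Other groups also held genes that moved in both lines. Of the glycolysis and hypoxia list 6 were higher and 4 lower, with the prolyl hydroxylase gene P4ha2 at -0.59 and -0.72 and Ndrg1 at 0.49 and 0.35. Of the imprinted genes 7 were lower and 2 higher, among them the maternally expressed H19 (-0.26 and -0.30) and the paternally expressed Dlk1 (-0.33 and -0.31), and median centring ended the call of H19 with shKdm5c#1 (-0.22, adjusted p = 0.430) and of Dlk1 with shKdm5c#2 (-0.27, adjusted p = 0.0530). Against IB10, H19 was not called with either hairpin (-0.02 and -0.05, adjusted p = 0.630 and 0.113) and Ndrg1 not with shKdm5c#2 (0.07, adjusted p = 0.0580). The Polycomb-associated gene Phf1 gave 0.29 and 0.41, with the first call lost under median centring (0.33, adjusted p = 0.128).

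Genes called in both knockdowns had 1777 further probes, of which 1323 lay in the direction of the brightest probe, 539 were called in it and 18 were called in the opposite direction. Ratios computed here correlated with those of the authors at r = 0.963 to 0.977 per array.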
